A study of Mus musculus with 12 samples.

How the data were processed

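RNA from sorted splenic CD4 T cells of female MRL/Faslpr mice was measured on 12 Affymetrix whole-genome mouse arrays. MRL/Faslpr is a lupus-prone strain that carries a mutant allele of the death receptor gene Fas. The labels give 4 populations of 3 arrays each. Their TCRb+ CD4+ B220- gate was split by CD44, CD62L and PSGL1 (a selectin ligand encoded by Selplg). Per the labels and the series' design text, 3 CD44+ populations came from mice aged 16 to 24 weeks, and the naive CD62Lhi CD44lo cells came from mice aged 6 to 8 weeks. Population and age therefore cannot be told apart in the comparisons with naive cells. The sample titles call the 3 arrays of a group technical replicates, whereas the design text describes 3 independent sorts, and p-values measure only the spread between these samples. The description field of the CD62Llo PSGL1hi samples names another gate, and the titles and design text were followed.

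The deposited values are linear ratios. Per the labels the signals came from MAS5, and its version and target scaling are not given in the sources used here. From the values themselves, each probe set was divided by its own median over the 12 arrays: the median was within 0.002 of 1 for 99.7% of the 45101 probe sets, and no value was 0 or negative. A ratio therefore compares arrays for 1 probe set, and gives neither the brightness of a probe set nor its rank against other probe sets. No detection call or background level was used here, so signal over background is unknown. The median ratio of an array lay between 0.967 and 1.022, and no further scaling was applied.

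The design had assumed MAS5 signals. Because the values are ratios, 4 choices made for signals were replaced. No pseudocount was added, no filter on dim probe sets was applied, the prior variance of limma was fitted without a trend, and the probe set of a gene was chosen by its annotation instead of its brightness. The platform annotation gave 1 gene symbol to 34945 probe sets and several to 932; 9160 probe sets were not listed and 64 were array controls. For each of 18193 genes the probe set kept was one without cross-hybridisation suffix and with a curated RefSeq target where available, the lowest numbered first; 9183 genes had 1 probe set and 9010 had several. Entrez identifiers matched 18032 genes to RefSeq, with no symbol changed. Genes without a named probe set are not reported here.

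Values were taken to log2 and fitted with limma 3.58.1 in R 4.3.3 with version 1.17.8 of data.table, with lmFit and eBayes on all 12 arrays and 1 mean per population. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes. The pooled spread had 8 residual degrees of freedom, with a prior of 7.31 degrees of freedom. An F test asked which genes differed among the 4 populations, followed by 6 pairwise comparisons, 3 of them main (PSGL1lo against PSGL1hi at low CD62L, low against high CD62L at high PSGL1, and PSGL1lo against naive) and 3 of second rank. Errors of log2 differences are standard errors of the fit. The typical precision was a standard error of 0.118 on the log2 scale, the median over genes; the number of arrays limits it.

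In each comparison 27 gene lists for T cell states, programmes and other cell types, and a list of gate genes, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within the comparison. Counts of list members are given over all genes and, in most places, also adjusted over the list alone. Camera was repeated with the correlation estimated from the data, and fry tested whether the genes of a list moved, on balance, one way. Selplg and Cd44, which define the gates, were left out of lists and rankings. Genes named were the gate genes and Fas in each comparison, the 8 largest rises and 8 largest falls (4 and 4 in second-rank comparisons) among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, and a fixed set of T cell state genes. A planned minimum on the brightness of ranked genes could not be applied to ratios. Genes without an ordinary symbol were skipped in rankings. Comparisons, lists, the rule for named genes and the alternative settings were chosen before the data were examined, apart from the changes that the unit required.

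Arrays with the same replicate number were checked for pairing by correlating their deviations from the group means over genes. Between effector populations every correlation was above 0.1: 0.373, 0.137 and 0.126 for PSGL1lo with CD62Llo PSGL1hi, 0.345, 0.278 and 0.456 for CD62Llo PSGL1hi with CD62Lhi PSGL1hi, and 0.283, 0.109 and 0.263 for PSGL1lo with CD62Lhi PSGL1hi, so a replicate block is given where it changes a call in these comparisons. Correlations with naive arrays ranged from -0.132 to 0.215 and showed no pairing.

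The fit was tested on simulated data for the PSGL1lo comparison with CD62Llo PSGL1hi over 18193 genes. It recovered 49.3% of 67 genes changed by 0.5 on the log2 scale, 92.5% of 67 changed by 1 and 100% of 66 changed by 2. It made 8 false calls, and 0 calls in a contrast without changes. The simulated arrays were independent, and far fewer genes were changed than the 1965 called in the data. These shares therefore need not carry over to the data. Other settings comprised quantile normalization, centring of arrays on their median, all probe sets, the mean of a gene's probe sets, a variance trend over a gene's mean log ratio, array weights, only the 2 groups compared, a replicate block, a minimum change, and leaving out each array in turn. The probe set with the highest SD per gene and a replicate block within the 9 effector arrays were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.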

Results

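Gene expression was compared among 4 populations of splenic CD4 T cells from MRL/Faslpr mice, each on 3 arrays. Of the antigen-experienced CD44+ cells of aged mice, CD62Lhi PSGL1hi cells are high in both homing molecules. CD62Llo PSGL1hi cells are low in CD62L, and CD62Llo PSGL1lo cells are low in both. Naive cells of young mice were the reference. The question posed by the design is how the effector populations differ from each other and from naive cells. Values are ratios of a probe set's signal to its own median over the 12 arrays, and differences are on the log2 scale ± SE (n = 3 arrays per population). The median SD between the 3 arrays of a population ranged from 0.104 for naive to 0.149 for CD62Llo PSGL1lo cells.

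RNA of the gate genes followed the sort. Selplg had a ratio of 0.133 ± 0.0182 (SD, n = 3) in CD62Llo PSGL1lo cells, against 0.993 ± 0.0955 in CD62Llo PSGL1hi cells, and was lower by -2.91 ± 0.12 (adjusted p = 9.21e-11). Cd44 encodes the receptor that marks antigen-experienced T cells. It had a ratio of 0.0791 ± 0.00462 in naive cells. It was 16-fold higher in PSGL1lo cells (adjusted p = 1.64e-12), 3.80 ± 0.12 higher on the log2 scale in CD62Llo PSGL1hi and 3.45 ± 0.12 higher in CD62Lhi PSGL1hi cells. Of 3 other Cd44 probe sets 1 showed no such difference. Cd4 RNA was 0.59 ± 0.10 higher in CD62Llo PSGL1hi than in CD62Lhi PSGL1hi cells (adjusted p = 0.00223; 0.0806 with the probe set of the highest SD). Ptprc, which encodes the leukocyte antigen CD45, differed by at most 0.13 on its main probe set and by up to 0.48 on another, with no call on either. Fas RNA, whose gene is mutated in this strain, was 0.53 ± 0.14 higher in PSGL1lo than in naive cells (adjusted p = 0.0115; 0.0661 without naive replicate 2, and 0.0667 after quantile normalization). Between PSGL1lo and CD62Llo PSGL1hi cells Fas differed by 0.38 ± 0.14 (adjusted p = 0.125; 0.0265 without CD62Llo PSGL1hi replicate 2, and 0.0279 with a replicate block within the 9 effector arrays). Among the 4 populations 5128 of 18193 genes differed (28.2%).

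**Figure D1:**
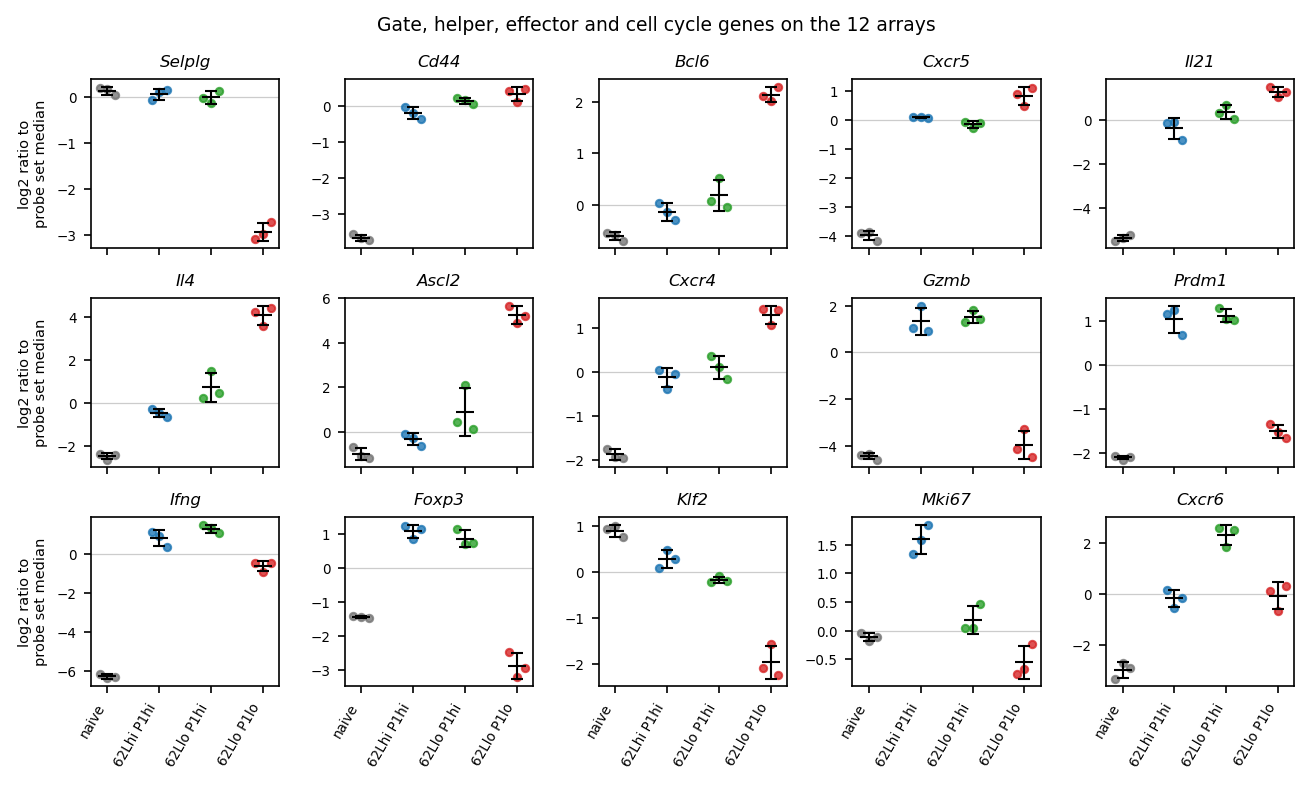
Each panel shows 1 gene: points are the 3 arrays of a population (62L, CD62L; P1, PSGL1), the vertical axis is the log2 ratio to the probe set's median over the 12 arrays, and bars are the mean ± SD. Selplg is low in CD62Llo PSGL1lo cells alone among these 4 populations, Cd44 is low in naive cells, Bcl6, Il4 and Ascl2 are highest in PSGL1lo cells, and Gzmb, Prdm1 and Foxp3 are lower there than in the PSGL1hi effector populations.

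Among CD62Llo cells, low PSGL1 went with lower RNA of cytotoxic and Th1 genes and with higher RNA of genes for B cell help. With an estimated correlation the list call held for the former (adjusted p = 0.00345) and was lost for the latter (adjusted p = 0.141). NK and CD8 T cell markers were lower too, for 4 of 11 genes (camera adjusted p = 0.000263; adjusted p = 0.266 with an estimated correlation). Bcl6, the repressor that directs follicular helper T cell differentiation, was 1.95 ± 0.14 higher in CD62Llo PSGL1lo than in CD62Llo PSGL1hi cells, a 3.87-fold difference (adjusted p = 6.47e-08). The helper cytokine gene Il4 was 3.33 ± 0.26 higher, and Ascl2, a transcription factor that promotes follicular helper cells, was 4.38 ± 0.36 higher. Granzyme B, a killing protease encoded by Gzmb, was lower by -5.50 ± 0.28, and Foxp3, the lineage factor of regulatory T cells, by -3.74 ± 0.17, 13.4-fold lower (adjusted p = 3.36e-10). Of 18193 genes, 1965 differed, 844 higher and 1121 lower. The split turned without PSGL1lo replicate 2, when 2093 differed, 1192 higher and 901 lower, and 1647 of the 1965 calls were kept in the same direction.

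The largest rises in PSGL1lo cells, after Ascl2, Il4 and the gate genes are set aside, were Fam71b (4.53 ± 0.25), the lysosomal protease gene Ctsl (3.93 ± 0.36), the cystatin-family gene Stfa3 (3.91 ± 0.38), the lipoprotein gene Apoe (3.55 ± 0.35), Chn1 (3.46 ± 0.30) and the BMP and Wnt antagonist gene Sostdc1 (3.21 ± 0.28). The largest falls besides Gzmb were Ctla2a (-5.37 ± 0.19), the sialyltransferase gene St3gal6 (-5.20 ± 0.16), Ifitm1 (-4.85 ± 0.33), Gzmk (-4.71 ± 0.13), the NK receptor gene Klrd1 (-4.59 ± 0.29), the granule protein gene Nkg7 (-4.50 ± 0.11) and Esm1 (-4.48 ± 0.29). Adjusted p-values of these 13 genes were at most 2.58e-06. The other probe sets of Ctsl and Chn1 did not pass the threshold, nor did 3 of 4 others of St3gal6.

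Of 28 genes tested for B cell help, 17 were higher and 2 lower in PSGL1lo cells, 21 and 2 adjusted over the list alone (camera adjusted p = 1.57e-16; adjusted p = 0.141 with an estimated correlation). Cebpa rose by 2.85 ± 0.21 and Pdcd1, which encodes the inhibitory receptor PD-1, by 1.62 ± 0.15. The follicle homing receptor gene Cxcr5 rose by 0.99 ± 0.14 (adjusted p = 9.61e-05), and Cxcr4, which encodes a receptor for the stromal chemokine CXCL12, by 1.20 ± 0.15. Il21 was 0.92 ± 0.20 higher (adjusted p = 0.00608), a call lost after quantile normalization (adjusted p = 0.569). The other Il21 probe set was 1.257 ± 0.168 higher (limma adjusted p = 0.000189 over all probe sets). Icos, the gene of a costimulatory receptor, differed by -0.06 ± 0.17 (adjusted p = 0.913) and Cd40lg by 0.24 ± 0.11 (adjusted p = 0.274).

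Of 26 Th1 and cytotoxic genes, 18 were lower and 1 higher in PSGL1lo cells, the same counts adjusted over the list alone (camera adjusted p = 6.81e-33; 0.00345 with an estimated correlation). Eomes, a transcription factor of cytotoxic cells, was lower by -4.43 ± 0.15, Ctsw by -3.45 ± 0.12, the Th1 factor Tbx21 by -2.11 ± 0.14 and the interferon gamma gene Ifng by -1.91 ± 0.18 (adjusted p = 1.81e-06). Prdm1, which encodes the repressor Blimp-1, was lower by -2.64 ± 0.14. Of 19 regulatory T cell genes 9 were lower and 1 higher, 10 and 3 adjusted over the list alone (camera adjusted p = 8.08e-06; adjusted p = 0.273 with an estimated correlation). Itgae was at -4.12 ± 0.21 and Gpr15 at -2.79 ± 0.27. The naive and central memory list had 5 of 25 genes higher and 9 lower, the same adjusted over the list alone (camera adjusted p = 0.0932; 0.0311 without PSGL1lo replicate 2). Within it the quiescence factor gene Klf2 was lower by -1.80 ± 0.15 and Il7r, which encodes the interleukin 7 receptor, by -0.80 ± 0.13, and Ccr7 differed by 0.12 ± 0.19 (adjusted p = 0.822). Gata3, the Th2 factor, differed by 0.28 ± 0.13 (adjusted p = 0.246).

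Genes of selectin ligand synthesis, which build the sugars that PSGL1 needs to bind selectins, had 7 of 19 members lower and 2 higher, 9 and 2 adjusted over the list alone (camera adjusted p = 0.000449; adjusted p = 0.273 with an estimated correlation). Besides St3gal6, the tyrosine sulfotransferase gene Tpst2 was lower by -1.73 ± 0.12 and the branching enzyme gene Gcnt1 by -1.34 ± 0.18. Of 39 adhesion and migration genes 22 were lower and 4 higher, 23 and 6 adjusted over the list alone (camera adjusted p = 2.04e-12; adjusted p = 0.12 with an estimated correlation). The chemokine receptor genes Ccr2 and Cxcr3 were at -4.43 ± 0.23 (-1.46 for another Ccr2 probe set) and -1.70 ± 0.12. Of 40 interferon response genes 11 were lower, 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.08e-06; adjusted p = 0.293 with an estimated correlation); Ifit3 was at -2.17 ± 0.16. Of 21 glycolysis genes 7 were higher, 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.57e-06; adjusted p = 0.441 with an estimated correlation). Hif1a, a factor that induces glycolytic genes, rose by 1.10 ± 0.15. Of 58 cell cycle genes 11 were lower, also adjusted over the list alone (camera adjusted p = 6.41e-05; adjusted p = 0.624 with an estimated correlation, and 0.207 after quantile normalization). Racgap1, for which 1 of 2 other probe sets did not pass the threshold, was at -1.66 ± 0.15.

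Camera did not call the next lists, whose genes went both ways or passed the threshold in small numbers. Cholesterol synthesis had 2 of 20 genes higher and 5 lower, 2 and 7 adjusted over the list alone (camera adjusted p = 0.0565; 0.0313 with a replicate block, and from 0.0385 to 0.0492 without 1 of 4 single arrays). Cytokines and TNF family ligands had 7 of 40 higher and 13 lower, 8 and 14 adjusted over the list alone (camera adjusted p = 0.118; 0.00437 after quantile normalization), where Il10 was at -3.36 ± 0.13 and Fasl at -2.99 ± 0.16. Higher and lower counts were 0 and 2 of 10 for Th2 genes (0 and 3 adjusted over the list alone), 1 and 3 of 10 for Th17 genes (3 and 3), 3 and 5 of 16 for inhibitory receptors (7 and 7), and 2 and 4 of 31 (2 and 4) for early genes induced through the T cell receptor. They were 2 and 4 of 26 for survival and death genes and 1 and 1 of 26 for the unfolded protein response, the same over the list alone. Among 31 cytosolic ribosomal protein genes 1 was lower, 0 over the list alone (camera adjusted p = 0.208; 0.0352 without PSGL1lo replicate 3). No gene of 42 for oxidative phosphorylation was called by limma; camera gave an adjusted p of 0.319, and 0.000226 without PSGL1lo replicate 2. Markers of other cells were 2 higher and 2 lower of 18 for B cells (3 and 3 over the list alone), 0 of 8 for plasma cells, 1 and 1 of 26 for macrophages, monocytes and neutrophils, 1 and 2 of 16 for dendritic cells (2 and 3), 0 of 7 for gamma-delta and innate-like T cells, 0 and 2 of 13 for erythroid cells and platelets, and 2 and 0 of 14 for stroma and endothelium, unchanged over the list alone where not given. Fry called 13 lists where camera called 9, adding Th2 (adjusted p = 1.26e-05), cytokines (0.000489), inhibitory receptors (0.000647), naive and central memory (0.032) and stromal genes (0.0386), and not calling cell cycle genes (0.162). Camera did call NK and CD8 T cell markers, lower in PSGL1lo cells for 4 of 11 genes, 6 adjusted over the list alone (camera adjusted p = 0.000263; adjusted p = 0.266 with an estimated correlation); Klrd1 and Cd7 (-1.75 ± 0.19) were among them, and Cd8a differed by -0.10.

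Among PSGL1hi cells, those low in CD62L had lower RNA of cell cycle genes than CD62Lhi cells. The list call was lost with an estimated correlation (adjusted p = 0.066), as were the other 6 list calls of this comparison. Ki-67, a nuclear protein of dividing cells encoded by Mki67, was lower by -1.41 ± 0.16, 2.65-fold (adjusted p = 0.000113). Cyclin B2 RNA (Ccnb2) was lower by -2.04 ± 0.23 and cyclin A2 RNA (Ccna2) by -1.90 ± 0.22. The chemokine receptor gene Cxcr6 was 2.48 ± 0.25 higher, 5.56-fold (adjusted p = 4.93e-05), and the TNF family ligand genes Tnfsf11, Tnfsf8 and Tnfsf13b rose by 1.43 ± 0.20, 1.42 ± 0.20 and 1.10 ± 0.16. In all, 394 genes differed, 135 higher and 259 lower. The count rose to 606 after quantile normalization, 285 higher and 321 lower, of which 370 were among the 394, and to 591 with a replicate block.

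Besides Cxcr6, the largest rises in CD62Llo PSGL1hi cells were Trgv1 (2.31 ± 0.20), Sostdc1 (1.97 ± 0.28), Pdzrn3 (1.76 ± 0.31), Adam8 (1.74 ± 0.15), Klrd1 (1.63 ± 0.29), Shtn1 (1.59 ± 0.22) and Lpar3 (1.58 ± 0.16). The largest falls were the tubulin gene Tubb2b (8.02-fold lower), the carboxypeptidase gene Cpm (-2.35 ± 0.12), Plxdc1 (-2.28 ± 0.14), the cyclins, Basp1 (-2.00 ± 0.20), the sororin gene Cdca5 (-1.88 ± 0.24), which acts in sister chromatid cohesion, and the proto-oncogene Myb (-1.87 ± 0.14). Klrd1 had an adjusted p of 0.00531 (0.05 with only the 2 groups in the fit). The other probe sets of Pdzrn3, Plxdc1 and Tnfsf13b did not pass the threshold, nor did 1 of 2 others of Slamf1.

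Cell cycle genes were lower for 38 of 58 members and higher for 0, 46 and 0 adjusted over the list alone, with a median difference of -1.06 (camera adjusted p = 1.05e-59; adjusted p = 0.066 with an estimated correlation). The Th1 and cytotoxic list had 6 of 26 genes higher and 0 lower, 13 and 0 adjusted over the list alone (camera adjusted p = 9.57e-11; adjusted p = 0.066 with an estimated correlation). Il18rap was at 0.99 ± 0.15 and Tnf at 0.56 ± 0.09. Cytokines and TNF family ligands were higher for 8 of 40 and lower for 1, 14 and 2 adjusted over the list alone (camera adjusted p = 1.44e-07; adjusted p = 0.0878 with an estimated correlation). Of 28 genes for B cell help 4 were higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 2.25e-06; adjusted p = 0.494 with an estimated correlation). Slamf1 was at 0.78 ± 0.10. Naive and central memory genes were lower for 5 of 25, 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.44e-07; adjusted p = 0.0878 with an estimated correlation). The kinase gene Txk was at -1.23 ± 0.14 and Lef1 at -0.82 ± 0.15. Camera also called cholesterol synthesis (lower, 1 of 20 genes, adjusted p = 0.00106; 0.501 with an estimated correlation) and the unfolded protein response (higher, 0 of 26 genes, adjusted p = 0.0118; 0.789 with an estimated correlation, 0.0904 without CD62Lhi PSGL1hi replicate 1 and 0.0839 without CD62Llo PSGL1hi replicate 1). The remaining 20 lists were not called. After quantile normalization 3 of them were, the regulatory T cell (adjusted p = 0.0103), inhibitory receptor (0.0488) and early response lists (0.0263), and without CD62Lhi PSGL1hi replicate 2 the macrophage, monocyte and neutrophil list was (0.0492). Fry called 4 lists and not B cell help (0.262), cholesterol synthesis (0.273) or the unfolded protein response (0.637).

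Among the fixed T cell state genes, Gata3 was 0.68 ± 0.13 higher (adjusted p = 0.0079; 0.0568 without CD62Llo PSGL1hi replicate 2). Il21 differed by 0.74 ± 0.20 (adjusted p = 0.0859; 0.0337 with a replicate block), Il7r by 0.46 ± 0.13 (adjusted p = 0.104; 0.0187 with a replicate block) and Ccr7 by -0.29 ± 0.19 (adjusted p = 0.712; 0.00495 without CD62Lhi PSGL1hi replicate 1). Bcl6 (0.32 ± 0.14), Foxp3 (-0.21 ± 0.17), Tbx21 (0.31 ± 0.14), Ifng (0.49 ± 0.18), Pdcd1 (0.41 ± 0.15), Cxcr4 (0.23 ± 0.15), Cxcr5 (-0.25 ± 0.14), Prdm1 (0.09 ± 0.14), Icos (0.07 ± 0.17) and Cd40lg (-0.12 ± 0.11) did not pass the threshold, with adjusted p from 0.273 upward; after quantile normalization Tbx21 and Ifng did (adjusted p = 0.018 and 0.0293).

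At the ends of the effector gates, PSGL1lo cells had lower cell cycle and cytotoxic RNA and higher helper RNA than CD62Lhi PSGL1hi cells. With an estimated correlation the cytotoxic and Th1 list call held (adjusted p = 0.0241), and those for cell cycle and helper genes were lost (adjusted p = 0.129 for each). Ascl2 was 5.59 ± 0.36 higher, Sostdc1 5.17 ± 0.28, Stfa3 4.95 ± 0.38 and Fam71b 4.80 ± 0.25. Gzmb was lower by -5.31 ± 0.28, Ctla2a by -5.13 ± 0.19, St3gal6 by -4.96 ± 0.16 and Gzmk by -4.67 ± 0.13 (adjusted p of these 8 genes at most 1.06e-07). In this comparison 2714 genes differed, 1230 higher and 1484 lower. Without PSGL1lo replicate 2 the split turned to 1627 higher and 1224 lower. Of 4 other St3gal6 probe sets 2 did not pass the threshold. Cell cycle genes were lower for 44 of 58 members, 52 adjusted over the list alone (camera adjusted p = 2.39e-34; adjusted p = 0.129 with an estimated correlation). Of 28 genes for B cell help 20 were higher and 1 lower, 22 and 2 adjusted over the list alone (camera adjusted p = 1.53e-19; adjusted p = 0.129 with an estimated correlation). Of 26 Th1 and cytotoxic genes 17 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 5.76e-19; 0.0241 with an estimated correlation). NK and CD8 T cell markers were lower for 3 of 11 genes, 5 adjusted over the list alone (camera adjusted p = 0.000896, and 0.239 with an estimated correlation). Cholesterol synthesis had 12 of 20 genes lower and 2 higher, 13 and 2 adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.335 with an estimated correlation). Idi1 was at -1.81 ± 0.22. Fas differed by 0.43 ± 0.14 (adjusted p = 0.054; 0.0214 with a replicate block).

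Against naive cells, PSGL1lo cells had higher RNA of helper genes and of some Th1 genes, and lower RNA of naive T cell genes and interferon response genes. With an estimated correlation the list call held for helper genes and for naive genes (adjusted p = 0.0179 for each). It was lost for Th1 and cytotoxic genes (adjusted p = 0.161) and for interferon response genes (adjusted p = 0.0787). Il21, the cytokine that follicular helper cells give to B cells, was 6.64 ± 0.20 higher, 100-fold (adjusted p = 2.32e-12; 2.68 ± 0.17 on its other probe set), Cxcr5 4.81 ± 0.14, Pdcd1 5.51 ± 0.15, Ifng 5.64 ± 0.18 and Bcl6 2.74 ± 0.14. Satb1, a chromatin organiser of thymocytes and naive T cells, was lower by -4.60 ± 0.18 (-2.36 on another probe set), and Ccr7, which encodes the lymph node homing chemokine receptor, by -2.77 ± 0.19, 6.84-fold (adjusted p = 9.05e-09). In total 4224 genes differed, 2026 higher and 2198 lower. Which side was larger is not settled: higher genes led with 2505 against 1792 without PSGL1lo replicate 2, 1913 against 1716 and 1754 against 1690 without naive replicates 1 and 2. They led with 794 against 442 among changes of at least 1 on the log2 scale. They also led with 2341 against 1975 after median centring, 1590 against 1366 after quantile normalization and 2556 against 2440 with array weights. The naive cells came from younger mice, so age and population are not separated here.

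After the genes above, the largest rises were Sostdc1 (8.79 ± 0.28), Gpm6b (6.60 ± 0.20), Il4 (6.54 ± 0.26), Itgb8 (6.29 ± 0.23), the transcription factor gene Maf (6.28 ± 0.25), Ascl2 (6.24 ± 0.36) and Rnf128 (5.88 ± 0.22), which encodes an E3 ubiquitin ligase tied to T cell anergy. The largest falls besides Satb1 were Lypd6b (-5.20 ± 0.16), Pdlim4 (-5.14 ± 0.35), Amigo2 (-4.84 ± 0.22), Dapl1 (-4.82 ± 0.24), Txk (-4.48 ± 0.14), Tent5a (-4.47 ± 0.15) and the neutrophil granule gene Ngp (-4.39 ± 0.21). Adjusted p-values of these 14 genes were at most 1.04e-08. Of 5 other Maf probe sets 1 did not pass the threshold, and another Amigo2 probe set was at -0.31.

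Of 28 genes for B cell help, 25 were higher than in naive cells and 0 lower, also adjusted over the list alone, with a median of 2.72 (camera adjusted p = 3.08e-33; 0.0179 with an estimated correlation). Naive and central memory genes were lower for 20 of 25 and higher for 1, 21 and 1 adjusted over the list alone (camera adjusted p = 7.73e-15; 0.0179 with an estimated correlation). Inhibitory receptor genes were higher for 12 of 16 and lower for 2, also adjusted over the list alone (camera adjusted p = 1.07e-10; 0.0179 with an estimated correlation). Lag3 was at 4.11 ± 0.14 and Ctla4 at 3.18 ± 0.13. Cytokines and TNF family ligands were higher for 19 of 40 and lower for 1, 21 and 1 adjusted over the list alone (camera adjusted p = 2.02e-10; 0.0307 with an estimated correlation). Th17 genes were higher for 6 of 10 and lower for 0, 6 and 1 adjusted over the list alone (camera adjusted p = 9.84e-05; 0.0179 with an estimated correlation). Rora was at 2.01 ± 0.12, although of 8 other Rora probe sets 1 fell by 0.44 and 2 did not pass the threshold. Of 19 regulatory T cell genes 11 were higher and 2 lower, 12 and 2 adjusted over the list alone (camera adjusted p = 1.75e-06; adjusted p = 0.161 with an estimated correlation). Its members went apart: Nrp1 (3.92 ± 0.11) and Tnfrsf4 (1.97 ± 0.13) rose, while Foxp3 was lower by -1.42 ± 0.17 (adjusted p = 7.35e-06).

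Th1 and cytotoxic genes were higher for 12 of 26 and lower for 4, also adjusted over the list alone (camera adjusted p = 5.3e-05; adjusted p = 0.161 with an estimated correlation, and 0.995 after quantile normalization). Cxcr3 (3.82 ± 0.12), Bhlhe40 (5.68 ± 0.18) and Tbx21 (2.49 ± 0.14) were higher, and Prdm1 was 0.60 ± 0.14 higher, a direction that turned after quantile normalization. Icos rose by 2.19 ± 0.17, Cxcr4 by 3.19 ± 0.15 and Gata3 by 1.27 ± 0.13; Il7r was lower by -0.50 ± 0.13 (adjusted p = 0.0104; 0.0516 without PSGL1lo replicate 3, and 0.0876 after quantile normalization), and Cd40lg differed by 0.12 ± 0.11 (adjusted p = 0.53).

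Interferon response genes were lower in PSGL1lo than in naive cells for 25 of 40 members and higher for 0, 29 and 0 adjusted over the list alone, with a median of -0.65 (camera adjusted p = 1.92e-11; adjusted p = 0.0787 with an estimated correlation). Oas2, an antiviral RNA sensor, was lower by -4.11 ± 0.20, Usp18, which restrains interferon signalling, by -3.85 ± 0.23, and Ifit3 by -3.81 ± 0.16. In CD62Llo PSGL1hi cells 17 of the 40 were lower than in naive cells and 1 higher, 22 and 1 adjusted over the list alone (camera adjusted p = 3.27e-07; adjusted p = 0.132 with an estimated correlation). In CD62Lhi PSGL1hi cells these were 22 and 1, 27 and 2 adjusted over the list alone (camera adjusted p = 7.19e-10; adjusted p = 0.0745 with an estimated correlation).

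Glycolysis genes were higher in PSGL1lo than in naive cells for 14 of 21 and lower for 1, also adjusted over the list alone (camera adjusted p = 1.15e-06; adjusted p = 0.22 with an estimated correlation). Hif1a was at 2.77 ± 0.15 (1.15 on another probe set) and Tpi1 at 2.50 ± 0.21. Cholesterol synthesis genes were lower for 10 of 20 and higher for 2, 11 and 2 adjusted over the list alone (camera adjusted p = 0.000296; adjusted p = 0.22 with an estimated correlation). The epoxidase gene Sqle was at -1.99 ± 0.12. Of 31 ribosomal protein genes 10 were lower, also adjusted over the list alone (camera adjusted p = 0.000296; adjusted p = 0.403 with an estimated correlation). Adhesion and migration genes were higher for 19 of 39 and lower for 8, 21 and 10 adjusted over the list alone (camera adjusted p = 2.55e-05; adjusted p = 0.204 with an estimated correlation, and 0.0826 after quantile normalization). Survival and death genes were higher for 10 of 26 and lower for 5, 11 and 5 adjusted over the list alone (camera adjusted p = 0.00743; adjusted p = 0.3 with an estimated correlation). The inflammatory caspase genes Casp4 (3.94 ± 0.16) and Casp1 (3.44 ± 0.18) were among the rises.

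Some markers of other cells moved with the naive comparison. Some transcripts of neutrophil granules were lower in PSGL1lo than in naive cells, Ngp as above, S100a9 at -3.68 ± 0.19, Ltf at -3.15 ± 0.19 and Camp at -3.05 ± 0.13. Others were higher, Pglyrp1 by 1.48 ± 0.15, Mpo by 0.87 ± 0.21, Ctsg by 0.78 ± 0.16 and Prtn3 by 0.63 ± 0.19. Of 26 macrophage, monocyte and neutrophil markers 7 were lower and 2 higher, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00624; adjusted p = 0.378 with an estimated correlation). Plasma cell genes were higher for 4 of 8, also adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.228 with an estimated correlation). The immunoglobulin gene Ighm was at 3.74 ± 0.25 and the joining chain gene Jchain at 2.59 ± 0.26. Of 10 other Ighm probe sets 5 did not pass the threshold. NK and CD8 T cell markers were higher for 0 of 11 and lower for 5, 0 and 6 adjusted over the list alone (camera adjusted p = 0.00199; adjusted p = 0.204 with an estimated correlation). B cell genes were higher for 3 of 18 and lower for 7, also adjusted over the list alone (camera adjusted p = 0.111), with the B cell surface gene Ms4a1 at -2.00 ± 0.26.

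**Figure D2:**
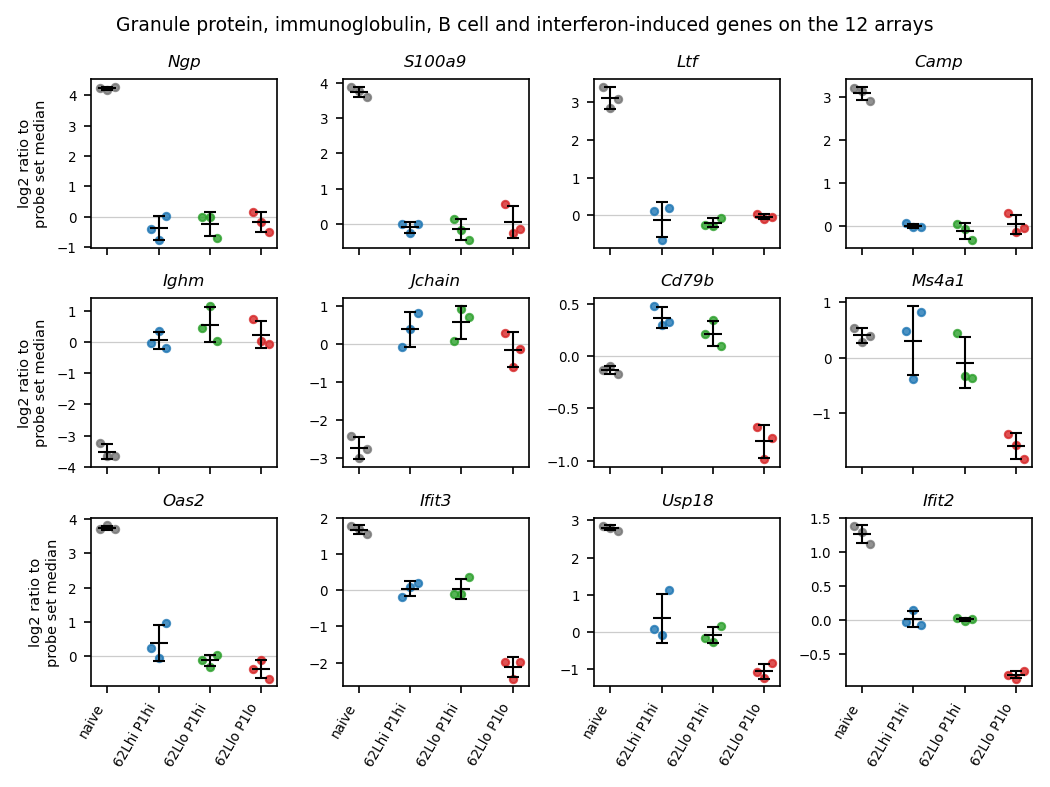
Points are single arrays of a population (62L, CD62L; P1, PSGL1), the vertical axis is the log2 ratio to the probe set's median over the 12 arrays, and bars are the mean ± SD of 3 arrays. Granule genes (Ngp, S100a9, Ltf, Camp) and interferon-induced genes (Oas2, Ifit3, Usp18, Ifit2) are highest in naive cells, and Ighm and Jchain are lowest there.

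Both PSGL1hi effector populations differed from naive cells in cytotoxic and Th1 genes and, like PSGL1lo cells, in helper and naive T cell genes. Ifng was 7.55 ± 0.18 higher in CD62Llo PSGL1hi and 7.05 ± 0.18 higher in CD62Lhi PSGL1hi cells, 187-fold and 133-fold (adjusted p = 1.25e-13 and 2.89e-13). The granzyme gene Gzmk was 6.21 ± 0.13 and 6.17 ± 0.13 higher, the chemokine gene Ccl3 6.54 ± 0.14 and 5.80 ± 0.14, and the enkephalin precursor gene Penk 6.22 ± 0.22 and 5.97 ± 0.22. Amigo2 was lower by -4.73 ± 0.22 and -4.35 ± 0.22, and Ngp by -4.46 ± 0.21 and -4.60 ± 0.21. The other Amigo2 probe set did not pass the threshold. The remaining leading falls were Pdlim4 (-4.89 ± 0.35) and Dapl1 (-4.54 ± 0.24) in CD62Llo PSGL1hi cells and S100a8 (-3.98 ± 0.29) and Ampd1 (-3.94 ± 0.17) in CD62Lhi PSGL1hi cells. The counts were 3768 genes (1960 higher, 1808 lower) and 3766 genes (1935 higher, 1831 lower). With the mean of a gene's probe sets lower genes led narrowly, 2190 against 2158 and 2192 against 2109. They also led with 2878 against 2538 for CD62Llo PSGL1hi cells with array weights, and with 3898 against 3872 for CD62Lhi PSGL1hi cells over all probe sets.

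Th1 and cytotoxic genes were higher than in naive cells for 20 of 26 in CD62Llo PSGL1hi cells and lower for 0, 20 and 1 adjusted over the list alone (camera adjusted p = 1.15e-30; 0.00441 with an estimated correlation). In CD62Lhi PSGL1hi cells 18 were higher and 0 lower, 19 and 0 adjusted over the list alone (camera adjusted p = 6.92e-26; 0.00589 with an estimated correlation). Regulatory T cell genes were higher for 15 of 19 and lower for 1 in each, also adjusted over the list alone (camera adjusted p = 8.74e-17 and 1.22e-16; 0.019 and 0.0229 with an estimated correlation). In both populations camera called plasma cell (adjusted p = 0.00028 and 2.7e-05) and dendritic cell markers higher (0.0243 and 0.0469). It called macrophage, monocyte and neutrophil markers lower (0.0243 and 0.0364). None of these marker calls held with an estimated correlation (adjusted p from 0.117 upward). Genes for B cell help were higher for 23 of 28 in CD62Llo PSGL1hi and 21 in CD62Lhi PSGL1hi cells, and lower for 0. Their camera adjusted p was 4.44e-25 and 8.27e-20 (0.019 and 0.0345 with an estimated correlation). Naive and central memory genes were lower for 17 and 15 of 25, and higher for 0. Their camera adjusted p was 6.53e-16 and 5.06e-13 (0.012 and 0.0229 with an estimated correlation). Inhibitory receptor genes were higher for 12 of 16 in each. Of the 58 cell cycle genes 45 were higher than in naive cells and 0 lower in CD62Lhi PSGL1hi cells, 46 and 0 adjusted over the list alone, with a median of 1.00 (camera adjusted p = 2.1e-22; adjusted p = 0.092 with an estimated correlation). In CD62Llo PSGL1hi cells 9 were higher and 3 lower, 10 and 3 adjusted over the list alone (camera adjusted p = 0.648). In PSGL1lo cells 4 were higher and 18 lower, 5 and 23 adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.672 with an estimated correlation). That call was lost without PSGL1lo replicate 1 (0.0519), PSGL1lo replicate 2 (0.124) or naive replicate 1 (0.0557).

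**Figure D3:**
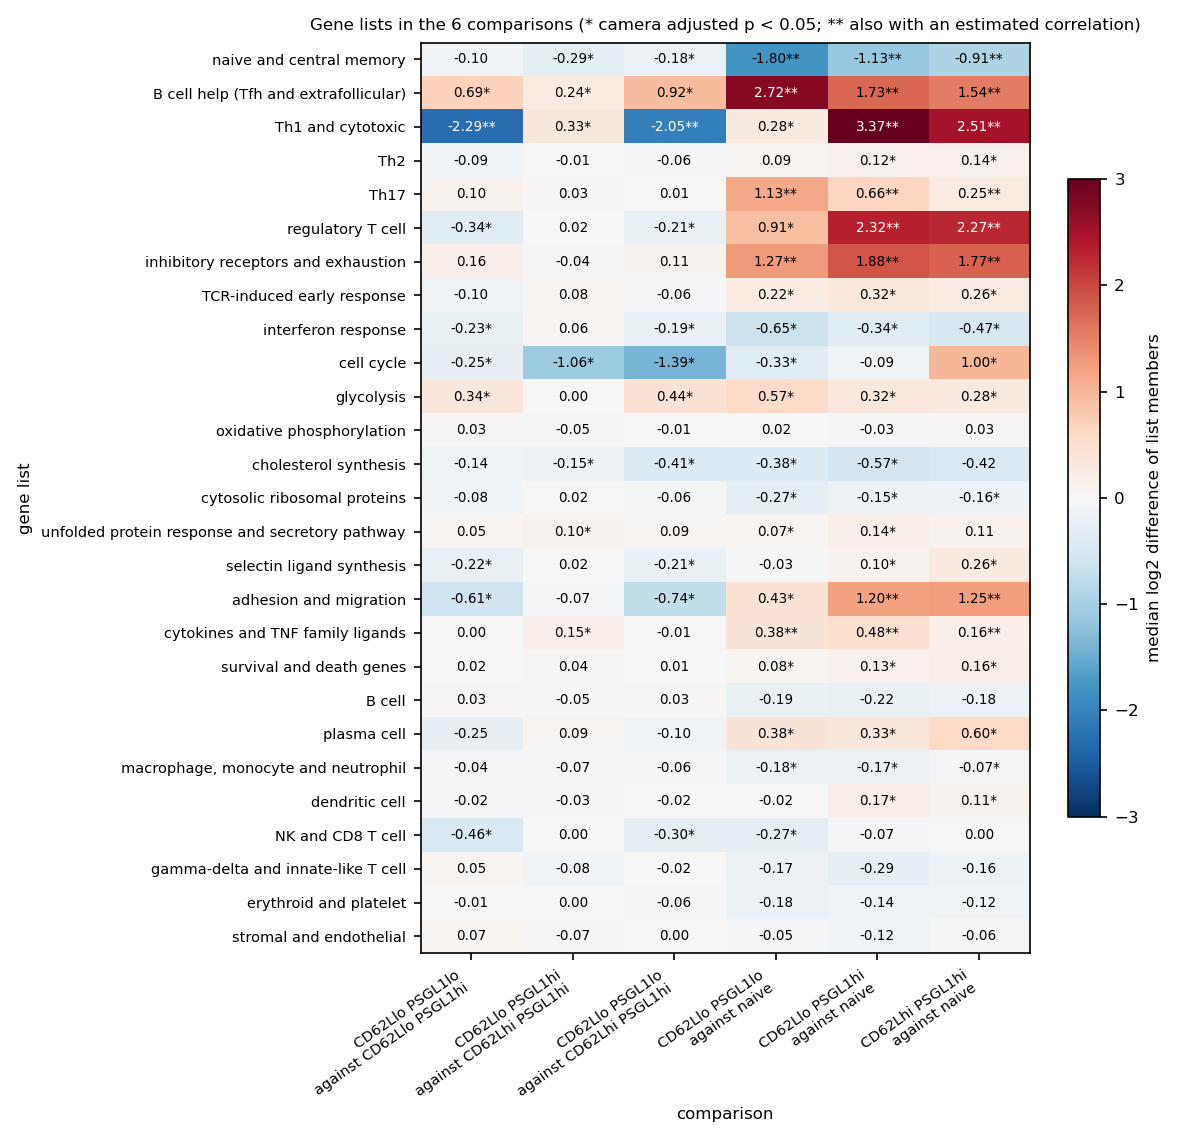
Colour and number give the median log2 difference of a list's tested genes (gene lists from top to bottom, the 6 comparisons from left to right; the population named first minus the other), with 1 star where camera's adjusted p was under 0.05 and 2 stars where it was also with an estimated correlation. Cell cycle genes have a median of -1.06 in CD62Llo PSGL1hi against CD62Lhi PSGL1hi cells and 1.00 in CD62Lhi PSGL1hi against naive cells, and Th1 and cytotoxic genes -2.29 in PSGL1lo against CD62Llo PSGL1hi cells.

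Over the 6 comparisons camera called 85 of 162 list tests, the gate genes aside, of which 23 were also called with an estimated correlation. In the 4 other comparisons fry called 15 lists for PSGL1lo against CD62Lhi PSGL1hi cells, where camera called 11, and 20, 21 and 20 lists against naive cells, where camera called 19, 20 and 19. Cell cycle genes in PSGL1lo against naive cells were among the calls that fry lost (adjusted p = 0.167), and B cell genes there among those it added (0.00886). Genes whose 3 values in one population did not overlap the 3 in the other made up 22.7% of the 18193 genes for PSGL1lo against CD62Llo PSGL1hi cells, 15.4% for CD62Llo against CD62Lhi PSGL1hi cells and 23.3% for PSGL1lo against CD62Lhi PSGL1hi cells, where chance gives 10%. Against naive cells the shares were 36.1%, 40.6% and 35.7% for PSGL1lo, CD62Llo PSGL1hi and CD62Lhi PSGL1hi cells.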

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

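The tests of macrophage RNA and of B cell RNA below were chosen after the results were seen. The array carries controls that no comparison uses. The 5' control probe set for 18S ribosomal RNA had a ratio of 5.97 in CD62Llo PSGL1lo replicate 2, against 0.603 to 1.589 on the other arrays, and was picked out as a sample far from the others. Of 10092 probe sets without a single gene name, 1129 differed among the 4 populations, a smaller share than the 28.2% of the 18193 named genes. No comparison used these probe sets. The ratio of the 3' to the 5' Gapdh control probe set also differed between populations, 1.23 to 1.33 in naive, 0.732 to 0.909 in PSGL1lo and 0.901 to 1.06 in PSGL1hi cells, whereas that of beta-actin was 0.946 to 1.05, 0.96 to 1.04 and 0.984 to 1.31. Each deposited value was already divided by its probe set's own median. These control ratios therefore compare arrays only, and do not give the 3' to 5' ratio of signals on an array. Whether RNA integrity bears on the comparisons was not tested and stays open.

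The same array, CD62Llo PSGL1lo replicate 2, stood apart in its array weight (0.366) and in its deviation from the group mean (0.191 on the log2 scale). Whether it sets the calls between PSGL1lo and CD62Llo PSGL1hi cells was tested by leaving it out. In that fit 83.8% of the 1965 calls, 1647 genes, were kept in the same direction, so most calls did not need this array. A share above 80% had been set for excluding that explanation. Leaving out any other array of these populations kept fewer calls, from 1443 to 1622. The share kept thus also falls when an ordinary array is lost, and the bound cannot exclude an influence of this array. The array does turn the balance of higher and lower genes in all 3 comparisons of PSGL1lo cells, as given there.

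Some neutrophil granule transcripts (Ngp, S100a9, Ltf, Camp) were higher in naive cells than in all 3 effector populations, although the CD4+ TCRb+ gate would remove neutrophils. If neutrophil RNA had been carried into the naive sorts, other neutrophil transcripts might be higher too: 29.2% were (7 of 24, among them Chil3, Cd177 and Mmp8), against 5.71% of all genes. The bound set for that explanation was 30%, so it stays open. Pglyrp1 (2.13), Mpo (0.59), Ctsg (0.56) and Prtn3 (0.45, effector minus naive on the log2 scale) went the other way. Each was called in 1 or more of the 3 comparisons with naive cells. The median of 8 macrophage genes was -0.12 (naive minus effector), with quartiles of -0.262 and 0.095, so most were not clearly higher in naive cells. They ranged from -2.652 for Cd68, which was higher in effector cells, and -0.523 for Cd5l to 0.156 for Vcam1. The bound for macrophage RNA was chosen after the results were seen, so that explanation is not excluded. A difference with age in the transcripts of the T cells themselves stays open and was not tested, since young naive and aged effector mice are the only ones compared.

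Ighm and Jchain were higher in all 3 effector populations than in naive cells, although the gate kept CD4+ TCRb+ B220- cells, which would remove B cells and plasma cells. If plasma cell RNA had been carried into the effector sorts, other immunoglobulin genes might be higher too: 17.6% were (3 of 17: Igkv8-30, Igha and Igkv6-14), against 6.01% of all genes. That lies between the bounds set, and the explanation stays open. The median of the 18 B cell genes was -0.164 (effector minus naive), with quartiles of -0.393 and -0.057, so most were not higher in effector cells. Cd22 was, by 1.433. The bound for B cell RNA was chosen after the results were seen, so that explanation is not excluded. Age as an explanation stays open and was not tested.

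Regrouping the 12 arrays in 100 ways, the real one included, gave as many as 5128 genes among the 4 populations in 1 of 100, the real grouping; the highest other count was 1779. Each pairwise comparison was regrouped in all 10 ways of its 6 arrays. The real grouping alone reached its count (1 of 10; 1965, 394, 2714, 4224, 3768 and 3766 genes in the order of the comparisons), and the highest other count was 0 each time. Every other grouping mixes arrays of both populations, so real differences between populations widen the spread within its groups. Low counts there are built into the check, and no conclusion is drawn from them. The same limit applies to the other regroupings of the 12 arrays, which also mix populations. With 10 groupings the share of groupings that reach the real count cannot fall below 0.05. Same-numbered effector arrays were correlated, and only 3 of the other groupings place the arrays of every such pair in different groups. The pairing thus limits this check further.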

How the results depend on the processing

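Counts of called genes kept within 1.5 times the reported count in 142 of 155 values, gene results kept their call in 14907 of 15453 and list results in 2698 of 2835. Of the gene results that did not, 368 were weaker, 175 stronger and 3 reversed, and of the list results 95 were weaker and 42 stronger. Many genes were named for large differences or small p in these data, which favours a kept call. Leaving out 1 array gave 8616 of the gene values. Uncalled results that changed sign were counted as kept, 38 for genes and 52 for lists. An estimated correlation ended 62 list calls. Testing all probe sets, more tests by construction, gave 10696 among the 4 populations, 3775 and 5242 for PSGL1lo against CD62Llo and CD62Lhi PSGL1hi cells, and 9044, 7772 and 7770 for PSGL1lo, CD62Llo PSGL1hi and CD62Lhi PSGL1hi cells against naive cells. Asking for a change of at least 1 on the log2 scale, a stricter rule, left 544, 140 and 742 genes between effector populations and 1236, 1006 and 1001 against naive cells, in the order of the comparisons. Quantile normalization, which forces equal spreads on the arrays, gave 606 for CD62Llo against CD62Lhi PSGL1hi cells, and turned Prdm1 (-0.27) and Il10 (-0.22) in PSGL1lo against naive cells. The probe set with the highest SD turned Ndufb8 (-0.12) in CD62Lhi PSGL1hi against naive cells. The cause was not tested for these 4 values.

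Leaving out 1 array at a time gave 4177 to 5564 genes among the 4 populations, 1475 to 2093 for PSGL1lo against CD62Llo PSGL1hi, 265 to 474 for CD62Llo against CD62Lhi PSGL1hi, and 3444 to 4360 for PSGL1lo against naive cells. A replicate block gave 2406, 591 and 3179 genes between effector populations and, although arrays showed no pairing there, 4805, 4374 and 4307 against naive cells. Beyond the blocked values printed with the comparisons, it changed no other call among the results given. Settings with a pseudocount and a stricter filter on dim probe sets were not run, because the values are ratios, and for the same reason signal over background is unknown.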

Other observations

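Of 31 early genes induced through the T cell receptor, more were higher than lower against naive cells in each effector population, and no call held with an estimated correlation. In PSGL1lo cells 12 were higher and 3 lower, 14 and 6 adjusted over the list alone (camera adjusted p = 0.00182; adjusted p = 0.22 with an estimated correlation), in CD62Llo PSGL1hi cells 14 and 1, 15 and 2 over the list alone (3.06e-06; 0.093), and in CD62Lhi PSGL1hi cells 12 and 4, 14 and 4 over the list alone (0.00022; 0.158). Irf4, a factor that scales with receptor signal strength, rose by 2.70 ± 0.10, 2.46 ± 0.10 and 2.24 ± 0.10, but its other probe set only by 0.59 in PSGL1lo cells, and without passing the threshold in the PSGL1hi populations. Egr2 rose by 1.65 ± 0.17, 1.47 ± 0.17 and 1.37 ± 0.17 in the same order. Myc went the other way, lower by -1.63 ± 0.14, -1.28 ± 0.14 and -1.06 ± 0.14.

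Of 19 genes of selectin ligand synthesis, 7 were higher and 2 lower in CD62Llo PSGL1hi than in naive cells, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.206 with an estimated correlation). In CD62Lhi PSGL1hi cells these were 9 and 2, 11 and 3 over the list alone (0.00171; 0.166), and in PSGL1lo cells 5 and 4, also over the list alone (0.903). Tpst2, which adds the sulfates that PSGL1 needs to bind P-selectin, was 1.01 ± 0.12 and 0.70 ± 0.12 higher in the PSGL1hi populations and lower by -0.73 ± 0.12 in PSGL1lo cells. Gcnt1 was higher in all 3, by 2.15 ± 0.18 and 2.35 ± 0.18 in PSGL1hi and 0.81 ± 0.18 in PSGL1lo cells.

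A hypothesis chosen after the comparisons were seen concerned the steps from high to low CD62L and then from high to low PSGL1. It was that both steps move genes the same way. The gates themselves give no order in time between the populations. Genes called in the same direction in both steps numbered 116, 5.22 times the 22.2 that independent calls would give, 40 higher (among them Sostdc1, Il4, Tnfsf8 and Vdr) and 76 lower (among them Basp1, Slamf7 and Depdc1a). Genes higher and then lower were also in excess, 46 against 8.32, while genes lower and then higher were not far from it, 16 against 12. The middle population enters both steps with opposite sign. The covariance of both steps over all genes was 0.00234, against -0.00847 in 100 simulations without effects, and the correlation 0.026 against -0.5. These simulations took the arrays as independent, although same-numbered effector arrays were correlated. Overlap of this kind may come from genes that vary among these populations in either direction, so a common direction of both steps was not shown.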
